A study of Mus musculus with 3 samples.

How the data were processed

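Single-cell RNA libraries were made with the 10x Genomics 3' chemistry, version 3.1, from dissected and trypsin-dissociated sensory epithelium of adult mouse cochlear explants, per the labels' protocols. The authors deposited filtered matrices of UMI counts per gene and barcode, 1 per library, with 31053 genes and 2395 barcodes in all. Per the submitters' processing notes, the tools were Cell Ranger 5.0, STAR and Seurat 3.2.2 and the genome build was mm10, also named GRCm38, while the matrix headers give a software version of 3.1.0, and the difference could not be settled from these sources. The role of each tool, and whether introns were counted, is not given in the sources used here. The libraries hold 512 (control), 788 and 1095 (Dox) barcodes, each with at least 500 UMIs. Gene positions are 1-based and come from the GENCODE M21 annotation of GRCm38, matched by gene identifier.

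Barcodes were kept with at least 200 genes and at most 20% mitochondrial UMIs, which left out 149, 152 and 98. Scrublet marked 1, 0 and 1 of the barcodes as doublets and was taken not to have worked, and no barcode was removed as a doublet in the reported values. Kept cells had medians of 2470, 3876 and 5200 genes and 2.93%, 3.32% and 3.57% mitochondrial UMIs. Little Malat1, a nuclear RNA, was found in 58 of the control cells (16.0%) and in 202 (31.8%) and 160 (16.0%) of the Dox cells. Cells were scaled to 10000 UMIs, log-transformed, reduced to 2000 variable genes and 30 principal components, and clustered by the Leiden method at resolution 1 with 15 neighbours (scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, Python 3.11.15). A cluster was called by a cell type where at least 3 of the type's markers were among its 25 leading genes, more than of any other type. The name was withheld from clusters of low depth with none of the type's markers among the top 10. In every named cluster, no other type had more markers among the top 10. Classes with at least 20 cells in each library were compared between treatments.

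UMI counts were summed per library over the cells of a class, giving 261383, 1980635 and 702499 UMIs for supporting cell-like cells, 297333, 811525 and 549823 for glia-like cells and 357357, 758155 and 684884 for macrophage-like cells. The sums were tested with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood F test, with TMM scaling, filterByExpr and Benjamini-Hochberg adjustment, and a gene was called at an adjusted p of 0.05 or less. The labels give pooled cultures per library and no more, so p-values measure the spread between 2 Dox libraries, which may be in part technical, with 1 residual degree of freedom. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry, and lists with fewer than 3 measured genes were left out. With an estimated correlation, camera rests on the 1 residual degree of freedom and could hardly call any list. Its adjusted p therefore cannot decide for or against a list. CPM of tested genes is TMM-scaled, while CPM of barcodes left out, and of Malat1 and Xist per cluster or library, is not. Folds against 0 counts are bounds at 3 counts over the group. The steps were tested on simulated counts with 200 changed genes. Among the 8321 genes of the supporting cell-like class, 15.2%, 44.8% and 81.0% of 2-, 4- and 8-fold changes were recovered, and 3 of 92 calls were unchanged genes. Among the 15426 genes of all cells the shares were 10.9%, 86.5% and 96.8%, with 8 of 139 calls unchanged. The simulation gave every gene 1 common spread, made rises and falls equally likely and let the control vary like the Dox libraries. It therefore gives no rate of false calls for the real data, where the spread of the lone control is unknown.

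Groups, tests, gene lists, cell type markers and the rule for named genes were fixed before the data were examined. The rule took the 12 largest rises and 12 largest falls in supporting cell-like cells, and 5 of each elsewhere, among genes with an adjusted p of 0.05 or less, at least 50 UMIs and both Dox libraries on the same side of the control, leaving out clone names, pseudogenes and mitochondrially encoded genes. It also took Myc and Notch1 in every comparison and up to 4 members per list by smallest p. Some genes that the rule took are not reported here. Alternatives were DESeq2's size factors, no low-count filter, DESeq2 1.42.0, edgeR's legacy fit, resolutions of 0.5 and 2, a strict cell filter (at least 500 genes, at most 10% mitochondrial), doublets left out, each library clustered alone, cells thinned to 1000 UMIs and each Dox library left out. Total count scaling, cells of little Malat1 left out and clustering without 2473 genes that were called or belong to the MYC, Notch and cell cycle lists were added later. Confidence intervals are 95% Clopper-Pearson intervals, and the limit given beside a share of 0 is 3 cells of the total. Both cover counting error only.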

Results

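Cochlear explants from adult mice of 4 to 6 weeks were cultured with or without doxycycline (Dox), and RNA was counted in single cells dissociated from the sensory epithelium. The mice carried rtTA, a transcription factor that needs Dox to bind DNA, and 2 transgenes under its control, Myc and the intracellular domain of Notch (NICD), the fragment that activates Notch target genes. Dox was given at 2 µg/ml for 4 days, and control cultures received water. The question was how supporting cells, the epithelial cells that surround the sensory hair cells, and the cells around them respond when both transgenes are switched on. There was 1 control library and there were 2 Dox libraries, each from 4 pooled cultures. No library came from Dox-treated cultures without the transgenes, so effects of the drug itself cannot be told apart from those of the transgenes. Unique molecular identifiers (UMIs), which mark single captured RNA molecules, summed to 5436731 in the control library, 20309102 in Dox replicate 1 and 33385927 in Dox replicate 2. After filtering, 363, 636 and 997 cells remained, with median depths of 6887, 16724.5 and 27579 UMIs per cell. Median depth over all kept cells was therefore higher in both Dox libraries, while class medians did not always follow: they were 1590, 8201 and 14149 UMIs in supporting cell-like, 9911.5, 17786.5 and 10593 in glia-like and 7810, 6991 and 21458 in macrophage-like cells.

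The cells fell into 19 clusters. The supporting cell-like class held 31 control cells and 59 and 29 Dox cells, and was named from Fabp7, Hes5, Gjb2, Sox2, Otog, Rorb, Gjb6 and Lfng. A Schwann or satellite glia-like class (28, 38 and 49 cells) was led by genes that include the myelin gene Pmp22, and a macrophage-like class (23, 50 and 29 cells) by Lyz2 and the complement genes C1qa, C1qb and C1qc. These were the classes compared between treatments. Values are listed as control, Dox replicate 1 and Dox replicate 2, CPM stands for TMM-scaled counts as edgeR's cpm function gives them in tested cells and for unscaled values in barcodes left out, and SE is the standard error of a log2 fold change.

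In supporting cell-like cells, Notch1 and several genes that respond to Notch rose with Dox, together with several genes of ribosome production and every measured ribosomal protein gene, while Hspa1a, Hspa1b and several genes of mature supporting cells fell. Notch1 (ENSMUSG00000026923, GRCm38 chromosome 2, 26457903 to 26516663, minus strand) was at 56.1, 469 and 489 CPM, a rise of 3.09 on the log2 scale (SE 0.28, 8.51-fold, adjusted p = 0.000546, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Myc (ENSMUSG00000022346, chromosome 15, 61985391 to 61990374, plus strand) was at 12.5, 43.0 and 69.7 CPM, and its log2 difference of 2.10 (SE 0.64) missed the threshold with an adjusted p of 0.0849 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, resting on 4 control UMIs. The 3' UMIs of both genes cannot be divided between transgene and endogenous gene. The Notch1 difference was 1.74 in thinned cells and 2.20 with each library clustered alone, past the threshold in neither, while the Myc difference passed it in 3 of 12 alternatives. Of 8321 genes tested, 415 rose and 195 fell at an adjusted p of 0.05 or less. Little Malat1, a nuclear RNA, was found in 38.7%, 57.6% and 44.8% of the cells of this class. With those cells left out, an alternative chosen after seeing the data, 276 genes were called, 272 of them among the 610, and the Notch1 difference was 3.06 and the ribosomal median 2.07. With total count scaling in place of TMM, the median of all genes shifted to -0.46 on the log2 scale and the split became 252 risen and 733 fallen, so that the share of rises went from 68.0% to 25.6%.

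The 12 genes that the rule took as the largest rises in supporting cell-like cells, by fitted log2 fold change, had 0 control UMIs. Their folds are lower bounds taken against 3 UMIs in the control. These bounds do not place them above genes with measured control UMIs, such as Nrarp and Fabp7, whose ratios given below are larger. Hes5 (ENSMUSG00000048001, chromosome 4, 154960923 to 154962371, plus strand), a transcriptional repressor induced by Notch and also used to name the class, was at 0, 172 and 93.5 CPM, at least 16.1-fold higher (adjusted p = 0.00217, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Ydjc was at least 7.75-fold higher, Sparcl1 at least 7.43-fold, the MYC-interacting gene Cdca7l at least 6.10-fold and the fucosyltransferase gene Fut9 at least 5.92-fold. Cox6b2, Plk2, Acsl5 and Itih5 were at least 5.64-, 5.55-, 5.23- and 5.04-fold higher, and Mmp15, Cib2 and Mcrip2 at least 4.63-, 4.40- and 4.27-fold. With each library clustered alone, the log2 differences of Plk2, Itih5, Mmp15 and Cib2 turned to -0.22, -2.40, -0.51 and -0.14, and that of Cib2 was negative in 4 of 12 alternatives and positive past the threshold in 2.

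Among the falls, the heat shock gene Hspa1a (ENSMUSG00000091971, chromosome 17, 34969190 to 34972156, minus strand) went from 221 CPM in the control to 7.06 and 7.92 CPM, a log2 fold change of -4.89 (SE 0.37, adjusted p = 0.000546, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Its near-identical neighbour Hspa1b changed by -3.96, and the division of UMIs between these copies is uncertain. Hspa1a and Hspa1b are on the list of immediate early and dissociation genes, and with a lone control library handling cannot be told apart from Dox. The forkhead factor gene Foxq1 changed by -4.41, the phospholipase gene Pla2g7 by -3.73, Meltf by -3.16 and the circadian repressor gene Nr1d1 by -3.02. Arl4c, Dpysl2, Lgals3, Crybb3 and the endothelin receptor gene Ednrb changed by -2.98, -2.89, -2.65, -2.61 and -2.51. Cst6, a secreted protease inhibitor and the most abundant gene of these, went from 1703 to 268 and 214 CPM, a log2 fold change of -2.81 (SE 0.21).

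All 26 ribosomal protein genes rose, with a median log2 fold change of 2.04, and all 26 also passed when adjusted over the list alone. Rpl3 was at 752, 4600.5 and 4741 CPM, a log2 fold change of 2.64, and Rps18 and Rpl32 changed by 2.70 and 2.41. Of 28 measured MYC-responsive growth genes, which serve ribosome production, nucleotide supply and protein folding, 17 rose and 0 fell, or 22 rose and 1 fell when adjusted over the list alone. Their median log2 fold change was 1.51, or 1.39 with zero-control genes at their bound. The nucleolar genes Npm1, Ncl and Nop58 changed by 2.23, 1.86 and 2.62, and the mitochondrial chaperone gene Hspd1 by 2.24. In a set test with limma's camera, the adjusted p was 2.06e-15 for ribosomal protein genes and 1.43e-10 for MYC-responsive growth genes, and with an estimated correlation between genes the adjusted p was 0.876 for both. With 1 residual degree of freedom, the test with an estimated correlation could hardly call any list, here and in the other classes. With every cell thinned to 1000 UMIs, the ribosomal median was 0.89.

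**Figure D1:**
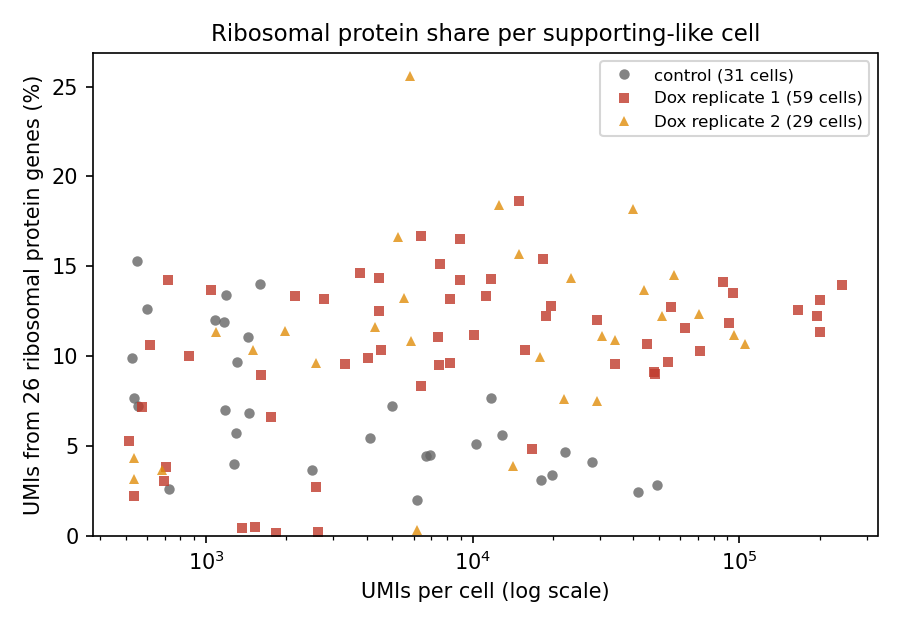
Percent of a cell's UMIs that came from the 26 ribosomal protein genes (vertical axis) against UMIs per cell on a log axis, 1 point per supporting cell-like cell, for 31 control, 59 Dox replicate 1 and 29 Dox replicate 2 cells. The median was 5.69% in control cells and 11.2% in each Dox library, and among cells with fewer than 5000 UMIs it was 7.65%, 9.23% and 9.97%.

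Notch-responsive genes split in supporting cell-like cells: 7 of 15 measured rose and 0 fell, or 8 rose and 1 fell when adjusted over the list alone, with a median log2 fold change of 1.73. The 7 include Notch1 itself, whose UMIs may come from the transgene, and Hes5, which was used to name the class. Nrarp (ENSMUSG00000078202, chromosome 2, 25180758 to 25183339, plus strand), a feedback regulator induced by Notch, was at 6.24, 376 and 223 CPM, a ratio of 53.6 with a counting interval of 14.8 to 443 on 2 control UMIs. The related repressor genes Hey1 and Heyl changed by 2.20 and 3.47, and the Notch ligand gene Jag1 by 1.76. The list as a whole missed the threshold in camera, with an adjusted p of 0.0520, and the adjusted p was 0.876 with an estimated correlation. Its median was 1.26 without Dox replicate 1, and 0.75 with each library clustered alone.

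**Figure D2:**
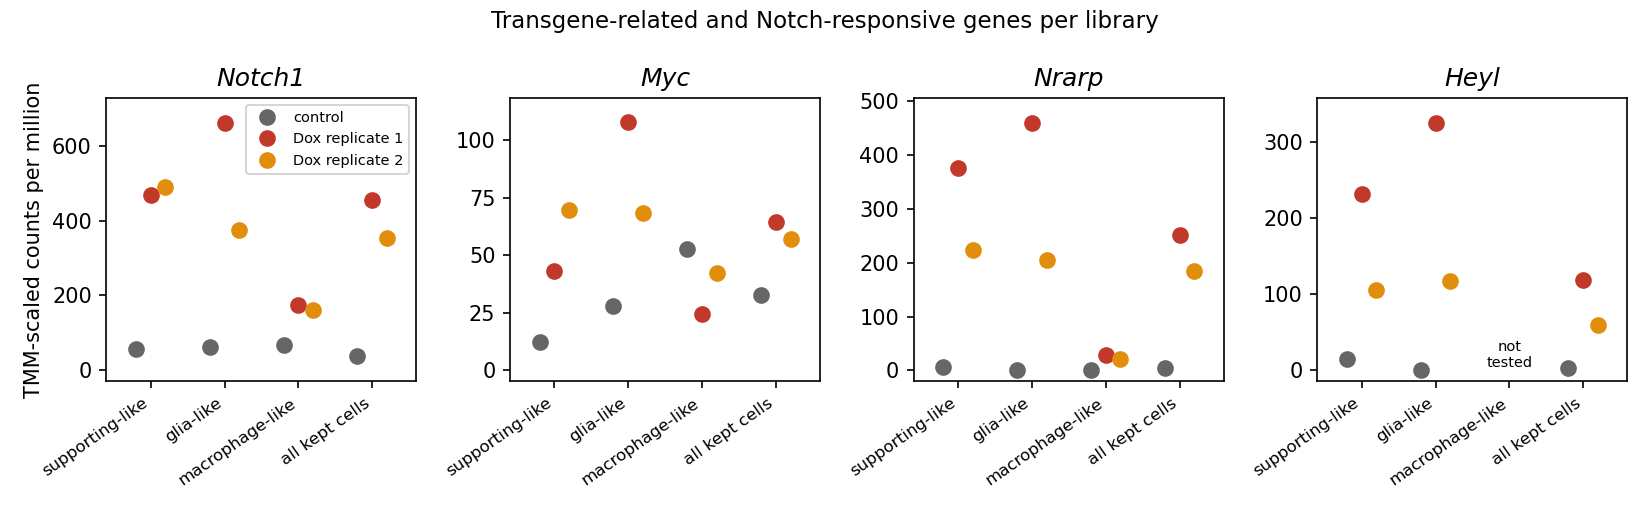
TMM-scaled CPM of Notch1, Myc, Nrarp and Heyl, 1 panel per gene and 1 point per library, in supporting cell-like, glia-like, macrophage-like and all kept cells. In supporting cell-like cells the Dox libraries stand at 469 and 489 CPM of Notch1 against 56.1 in the control, and in macrophage-like cells, where Heyl was not tested, at 175 and 161 against 66.7.

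Mitochondrially encoded genes also rose in the sums of supporting cell-like cells, 10 of 13, or 11 when adjusted over the list alone, with a median of 1.38 (camera adjusted p = 9.78e-05) and of 0.41 in thinned cells. The median mitochondrial share per cell did not rise, at 3.62% in the control and 3.46% and 3.45% in the Dox libraries. In the control sum, 3 of 31 cells held 45.3% of the UMIs. mt-Nd3, mt-Nd4l, mt-Cytb and mt-Nd2, which encode subunits of respiratory complexes, changed by 2.02, 1.84, 1.60 and 1.55. Of 25 nuclear genes of oxidative phosphorylation 3 rose, Cox4i1 and Cox5b by 1.19 each and Atp5d by 0.96, or 4 when adjusted over the list alone, with a median of 0.61 (camera adjusted p = 0.0159). Of 15 integrated stress response genes 2 rose, or 8 when adjusted over the list alone: Nupr1 by 2.75, and the serine synthesis gene Psat1, at least 2.48-fold higher. The median of that list was 1.45, or 1.03 with zero-control genes at their bound (camera adjusted p = 0.00359). Of 15 hypoxia genes 0 rose and 4 fell, in both adjustments, namely Vegfa (-1.21), the glucose transporter gene Slc2a1 (-1.59), Egln1 (-1.27) and Higd1a (-0.79), with a median of -0.63 (camera adjusted p = 0.0215). For each of these 4 lists the adjusted p with an estimated correlation was 0.876. The call was lost in 8 of 13 alternatives for Higd1a and in 7 of 12 for Psat1.

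Few genes of cell division had enough UMIs to be tested in supporting cell-like cells. Of 12 measured G2/M phase genes 2 rose in both adjustments, Mki67, at least 4.04-fold higher, and Cenpf, with a ratio of 13.8 and a counting interval of 3.78 to 115. The median of that list was 3.18, or 1.83 with zero-control genes at their bound, and 0.41 without Dox replicate 1 (camera adjusted p = 0.0265, and adjusted p = 0.876 with an estimated correlation). Of 9 S phase genes 0 rose and 0 fell in both adjustments by edgeR's quasi-likelihood test, with a median of 0.46, or -0.28 without Dox replicate 1 and -0.04 with total count scaling. These counts depended on which cells formed the class. At resolution 2, with 34, 103 and 90 cells, 10 of 28 G2/M phase genes rose (median 6.45, or 1.36 at the bound) and 7 of 28 S phase genes (median 2.99, or 1.51 at the bound). With the strict cell filter 8 of 12 G2/M phase genes rose (median 5.63, or 1.80 at the bound) and 1 of 13 S phase genes (median 1.16, or 0.59 at the bound). With each library clustered alone, 0 of 15 G2/M phase genes (median 2.79, or 2.39 at the bound) and 0 of 19 S phase genes (median 1.54, or 1.17 at the bound) rose. The cyclin gene Ccnd1 was at 9.36, 160 and 57.0 CPM, a ratio of 14.1 with a counting interval of 4.79 to 68.9 on 3 control UMIs, and its log2 difference was -0.25 with each library clustered alone.

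Of 19 measured genes of mature supporting cells 7 fell and 1 rose, or 7 fell and 3 rose when adjusted over the list alone. The glutamate transporter gene Slc1a3 changed by -2.24, the potassium channel gene Kcnj10 by -2.19 and Lgals3 by -2.65, while Sparcl1 rose. The list's median was -0.41 and its mean 1.06, which zero-control genes raise, and camera gave an adjusted p of 0.381. The median was -0.69 and -0.58 without Dox replicate 2 and without Dox replicate 1, -0.93 with total count scaling and -1.27 at resolution 2. The connexin genes Gjb2 and Gjb6 changed by -1.02 and -0.99, and among epithelial genes Epcam changed by -1.40 and Krt19 by 3.38. Fabp7, which marks both supporting cells and glia, had a ratio of 38.8 with a counting interval of 13.2 to 189. Of 14 otic progenitor genes 0 passed the test in either direction, with a median of 0.07, or 1 rose and 1 fell when adjusted over the list alone. Sox2, a progenitor and supporting cell factor, was at 131, 298 and 236 CPM, a log2 difference of 1.03 (adjusted p = 0.0533, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Of 5 measured hair cell genes Cib2 alone passed the test, a call that held in 2 of 12 alternatives.

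In other groups a few members changed in supporting cell-like cells. Of 13 interferon-stimulated genes 2 fell, H2-D1 and Ifit1, with log2 fold changes of -1.26 and -2.96, or 1 rose and 2 fell when adjusted over the list alone (median -0.94, camera adjusted p = 0.0520). In thinned cells the H2-D1 difference turned to 0.22, above the control. Of 13 p53 target genes 2 rose, Bax (1.92) and Plk2, or 3 rose and 2 fell when adjusted over the list alone. Of 17 NRF2-responsive genes, which respond to oxidants, 2 rose, Gstm1 (4.84) and Tkt (1.47), or 4 when adjusted over the list alone. Of 21 immediate early and dissociation genes 5 fell, among them Hspa1a, Hspa1b, Dusp1 (-1.49) and Klf6 (-1.02), or 1 rose and 5 fell when adjusted over the list alone. Of 35 lists, camera called 7, 6 higher and 1 lower, against 0 with an estimated correlation and 0 with limma's fry. No marker list of another cell type passed camera in this class.

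The 610 calls in supporting cell-like cells rest on the spread between 2 Dox libraries with 1 residual degree of freedom, and the lone control is assumed to vary like them. In the control, 3 of 31 cells held 45.3% of the UMIs, and edgeR's quasi-likelihood test called 0 genes with each library clustered alone (1277 at an unadjusted p of 0.05 or less, and 168 called by DESeq2). The control class then held 39 cells and 795766 UMIs at a median of 12927, against 31 cells and 261383 UMIs at a median of 1590. The calls thus depended on which control cells formed the class.

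In glia-like cells, Notch1, Myc and the Notch targets Nrarp and Heyl rose, 25 of 26 ribosomal protein genes, 7 of 20 sterol and lipid synthesis genes and 9 of 16 p53 targets rose, and several glial marker genes fell. Notch1 was at 61.9, 661 and 375 CPM, a log2 fold change of 3.07 (SE 0.43, adjusted p = 2.81e-05), and Myc at 27.8, 108 and 68.2 CPM, a log2 fold change of 1.67 (SE 0.47, adjusted p = 0.0257), both by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In thinned cells the Myc difference was -1.20, and its call was also lost in 3 further of 13 alternatives, with DESeq2's size factors, without the low-count filter and with DESeq2's Wald test. The Notch targets Nrarp and Heyl had 0 control UMIs and were at least 37.9- and 25.6-fold higher. The p53 target Zmat3, the fatty acid binding gene Fabp3 and Pdpn were at least 9.65-, 9.13- and 8.87-fold higher. The largest falls were in the chromatin gene Hmga2 (-6.26), Lgals1 (-5.62), the growth factor gene Btc (-5.36), the chemokine gene Cxcl10 (-5.04) and Plpp1 (-4.54). Of 7685 genes tested, 309 rose and 327 fell. With total count scaling the split was 259 risen and 584 fallen, and the share of rises 30.7% against 48.6%, with the median of all genes at -0.22 on the log2 scale.

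In glia-like cells 25 of 26 ribosomal protein genes rose, or 26 when adjusted over the list alone, with a median log2 fold change of 1.68 (camera adjusted p = 3.55e-15). Of 30 MYC-responsive growth genes 13 rose and 0 fell, or 18 when adjusted over the list alone, with a median of 1.35 (camera adjusted p = 5.49e-10), led by Nop58 (2.33), Srm (2.49), Nop56 (1.92) and Nolc1 (1.88). Of 20 sterol and lipid synthesis genes 7 rose, or 12 rose and 1 fell when adjusted over the list alone (median 1.26, camera adjusted p = 2.38e-05), including Idi1 (2.73), Fasn (2.13) and Cyp51 (2.09). Of 16 p53 targets 9 rose and 2 fell, or 11 and 2 when adjusted over the list alone (median 1.62 and 1.5 at the bound, camera adjusted p = 4.32e-05). Among them Gdf15 and Mdm2, the inhibitor of p53, changed by 2.21 and 2.37, and Plk2 by -1.91. Of 18 integrated stress response genes 4 rose, or 6 when adjusted over the list alone, with Nupr1 at 3.33 and the folate enzyme gene Mthfd2 at 2.13 (median 1.09, camera adjusted p = 2.95e-05). With an estimated correlation the adjusted p was 0.809 for each of these 5 lists.

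Of 17 NRF2-responsive genes 4 fell in glia-like cells, or 6 when adjusted over the list alone (median -0.59, camera adjusted p = 0.00199). These were Srxn1 (-2.62), Gstm1 (-1.64), Gclm (-1.35) and the ferritin gene Fth1 (-1.28). Of 11 glial markers 5 fell and 1 rose, or 8 and 1 when adjusted over the list alone (median -0.81, camera adjusted p = 0.0379). S100b went from 297 to 18.0 and 18.9 CPM (-4.00), the myelin gene Mbp changed by -1.58, and Fabp7 by 2.97. The interferon list (3 of 11 fell, or 6 fell and 1 rose when adjusted over the list alone, median -0.93), the otic progenitor list (Hmga2 and Sox2 fell of 6, or 3 when adjusted over the list alone, median -0.59) and the mitochondrially encoded genes (0 of 13 called in both adjustments, median 0.67) had camera adjusted p of 0.00635, 0.0106 and 0.00444. Of 12 Notch-responsive genes 6 rose, Notch1 itself among them, and 2 fell in both adjustments, with a median of 1.31 and a camera adjusted p of 0.0574. Of 30 lists camera called 10 and fry 2, and with an estimated correlation the adjusted p was 0.809 for each of the 10. DESeq2's Wald test called 175 genes in this class and thinned cells gave 119, against 636.

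In macrophage-like cells, the chemokine genes Cxcl13, Cxcl3 and Ccl2 fell and the neutrophil granule genes Camp and Ltf rose, while Mpo, also a neutrophil granule gene, fell, and Notch1 and Myc did not pass the test. Notch1 was at 66.7, 175 and 161 CPM, a log2 difference of 1.33 (SE 0.57, adjusted p = 0.419), and Myc at 52.8, 24.6 and 42.2 CPM, a log2 difference of -0.66 (SE 0.60, adjusted p = 0.970), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Barcodes left out by the cell filters carried Notch1 at 7.56, 308 and 220 CPM, without TMM scaling. Camp and Ltf, granule proteins of neutrophils, had 0 control UMIs and were at least 98.2- and 51.0-fold higher, and Adamdec1, Dnase1l3 and Pxdc1 at least 48.6-, 28.0- and 17.5-fold. Of 12 neutrophil markers 3 rose and 1 fell, or 4 and 2 when adjusted over the list alone, with a median of 0.02 (camera adjusted p = 0.119, and adjusted p = 0.982 with an estimated correlation). At clustering resolution 2, macrophage-like clusters held 19, 42 and 12 cells and neutrophil-like clusters 4, 8 and 17, which together number the 23, 50 and 29 cells of this class, and Camp, Ltf and Mpo were not among the genes tested in those macrophage-like clusters. The B cell chemokine gene Cxcl13 went from 189 control UMIs to 0, at least 244-fold lower. In the control, 3 of 23 macrophage-like cells held 50.6% of the UMIs of this class. With the barcodes that Scrublet marked left out, the control class held 22 cells and 272226 UMIs, against 357357 UMIs with them. That setting called 121 genes, 80 of them among the 103 called with all barcodes. The myeloid genes Mpo, S100a4 and Ms4a3 changed by -6.33, -5.18 and -4.90 and the chemokine gene Cxcl3 by -4.16. Of 7747 genes tested, 54 rose and 49 fell.

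Of 18 inflammatory and NF-kB genes 3 fell in macrophage-like cells, or 6 fell and 1 rose when adjusted over the list alone: Ccl2 went from 939 to 86.2 and 125 CPM (-3.15), and Ccl7 and Tnf changed by -2.75 and -2.61. The Tnf difference turned to 1.24 in thinned cells, and its call was lost in 3 further of 13 alternatives. The median was -1.02 (camera adjusted p = 0.000678). Of 27 S phase genes 0 were called in both adjustments, with a median of -0.64 (camera adjusted p = 0.000678). Of 26 ribosomal protein genes 0 were called in both adjustments, with a median of 0.48 (camera adjusted p = 0.0372), and of 28 MYC-responsive growth genes also 0, with a median of 0.19 (camera adjusted p = 0.929). Keratin and epithelial junction genes, which belong to other cells, had 1 of 9 risen, or 7 when adjusted over the list alone, with a median of 1.42 with zero-control genes at their bound (camera adjusted p = 0.032). Of 36 lists camera called 12, 8 higher and 4 lower, and with an estimated correlation the adjusted p was 0.982 for each. With no low-count filter, edgeR's quasi-likelihood test called 0 genes (593 at an unadjusted p of 0.05 or less, and 25 by DESeq2), and with the strict cell filter also 0 (508 unadjusted, and 25 by DESeq2).

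**Figure D3:**
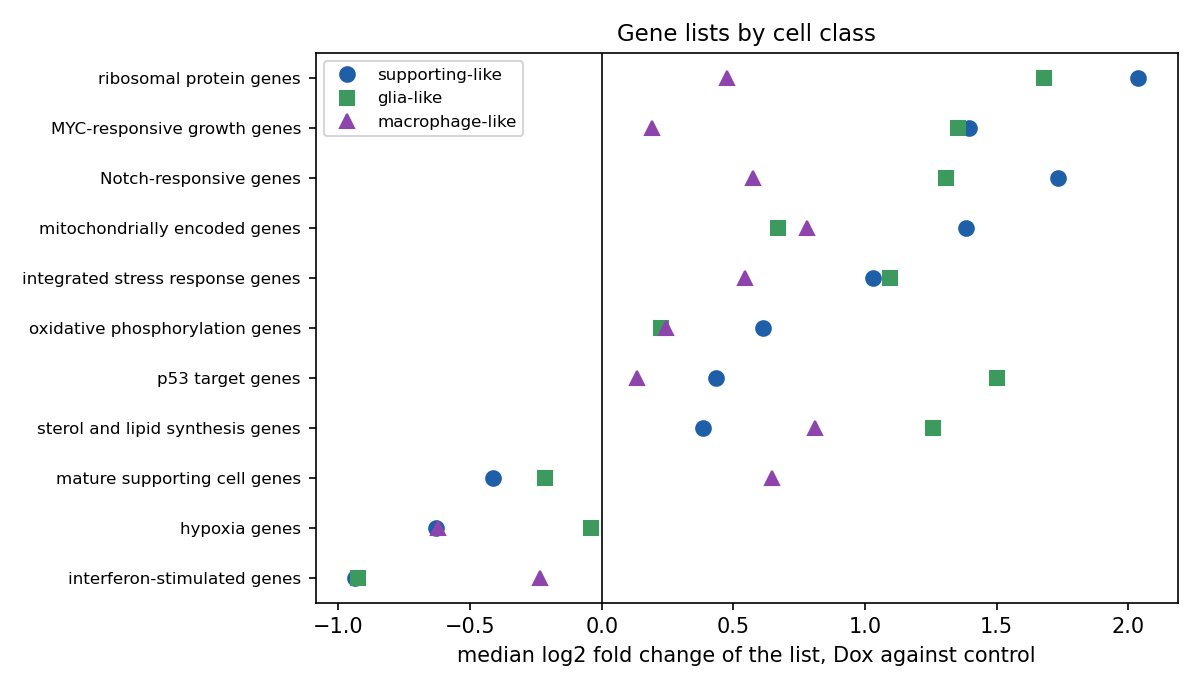
Median log2 fold change, Dox against control, of 11 gene lists in supporting cell-like, glia-like and macrophage-like cells, with zero-control genes at their bound. Ribosomal protein genes stand at 2.04, 1.68 and 0.48, and MYC-responsive growth genes at 1.39, 1.35 and 0.19.

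The Dox effects in supporting cell-like and glia-like cells were set against each other with a class-by-treatment term, with the library as a block. The effect on Notch1 differed by 0.01 on the log2 scale (SE 0.55). Of 9314 genes tested, the effect was higher in supporting cell-like cells for 101 and lower for 56. The p-values of this test are close to normal tails of the difference over its SE. They thus rest on a spread pooled over genes, not on each gene's own spread between libraries, and on 1 control library. Sox2 was among the higher ones, with a log2 fold change of 1.03 in supporting cell-like and -2.36 in glia-like cells, a difference of 3.36 (SE 0.45, adjusted p = 8.95e-11, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Ednrb was among the lower ones, at -2.51 and 0.80. NRF2-responsive genes had a median difference of 0.96 (camera adjusted p = 0.0204) and p53 targets of -0.88 (camera adjusted p = 0.0259), and with an estimated correlation the adjusted p was 0.942 for both.

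Against macrophage-like cells, a comparison chosen after seeing the data, the class-by-treatment term called 0 of 9843 genes by edgeR's quasi-likelihood test (683 at an unadjusted p of 0.05 or less, and no other tool was run). Ribosomal protein genes had a median difference of 1.47 (camera adjusted p = 1.58e-09) and MYC-responsive growth genes of 1.51 (camera adjusted p = 4.04e-07), and with an estimated correlation the adjusted p was 0.939 for both. In thinned cells the ribosomal medians of the classes were 0.89 and 0.90, the macrophage-like one 1.02 times the other, against 0.234 times in sums.

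Summed over all kept cells, Dox libraries had higher levels of Notch1, its target Nrarp, cell cycle and ribosomal protein genes and lower levels of several genes of fibroblasts, fibrocytes and bone cells. Such sums mix changes within cells with changes in the makeup of the libraries. Notch1 rose from 38.1 to 456 and 354 CPM (log2 fold change 3.41, SE 0.24, adjusted p = 0.0184) and Myc from 33.0 to 64.4 and 57.2 CPM (0.88, SE 0.17, adjusted p = 0.0472), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The Myc call was lost with total count scaling (0.59) and with cells of little Malat1 left out (0.86). Among the largest rises, Cyp4f15 was at least 10.6-fold higher, Nrarp changed by 5.51, the antimicrobial lectin gene Reg3g by 5.44 and Krt17 by 5.28, and Npw had a ratio of 42.8 with a counting interval of 7.64 to 1696 on 1 control UMI. The largest falls were in Inmt (-9.15), Cxcl13 (-7.92), the osteocalcin-related gene Bglap3 (-7.17), Mpo (-7.17) and the Wnt inhibitor gene Wif1 (-6.89).

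In all cells 25 of 28 G2/M phase genes rose, or 28 when adjusted over the list alone (median 1.63, camera adjusted p = 3.04e-11), with Ube2c at 1.95 and Mki67 at 1.90. Of 28 S phase genes 23 rose, or 28 when adjusted over the list alone (median 1.92, camera adjusted p = 3.04e-11), with Dtl at 3.37 and Hells at 2.68. All 26 ribosomal protein genes rose in both adjustments (median 1.32, camera adjusted p = 7.54e-11), as did 24 of 30 MYC-responsive growth genes, or 27 against 1 fallen when adjusted over the list alone (median 1.66, camera adjusted p = 1.81e-09). Of 18 TGF-beta-responsive and wound genes 15 fell, or 17 when adjusted over the list alone (median -2.31, camera adjusted p = 1.78e-08), among them Postn (-3.62) and Lox (-3.70). Of 7 osteoblast or osteocyte markers 6 fell, or 7 (median -4.62), of 15 fibrocyte markers 9, or 10 (median -2.19), and of 13 fibroblast markers 8, or 8 with 1 risen (median -2.21), the second number being adjusted over the list alone. Of 45 lists camera called 25, 10 higher and 15 lower, and with an estimated correlation the adjusted p was 0.747 for each.

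Of 15426 genes tested in all cells, 1148 rose and 1033 fell, against 881 and 2028 with total count scaling, where the share of rises was 30.3% against 52.6% and the median of all genes stood at -0.30 on the log2 scale. Thinned cells gave 888 calls.

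Shares of cells per class are given from a clustering without the changed genes, an alternative chosen after seeing the data, since genes that define the classes differed with Dox. The genes left out include those called over all cells, which partly reflect makeup, and the clusters were still named from all genes. Control fibroblast-like cells numbered 18 in this clustering and 114 in the planned one. These shares therefore do not stand free of the changed genes. Supporting cell-like cells made up 8.26% of control cells (95% exact Clopper-Pearson interval 5.65 to 11.6%), 9.59% of Dox replicate 1 (7.42 to 12.1%) and 3.91% of Dox replicate 2 (2.80 to 5.31%). The Dox libraries thus differed from each other by more than counting error. With each library clustered alone the shares were 10.7%, 9.43% and 4.31%, and at resolution 2 they were 9.37%, 16.2% and 9.03%, so that the side of the control on which a Dox library lay depended on the clustering. Glia-like cells made up 7.44%, 5.66% and 4.51%, macrophage-like cells 6.34%, 7.86% and 3.01%, fibroblast-like cells 4.96%, 4.87% and 8.32%, and pericyte-like cells 0.551%, 9.91% and 4.71%. In the planned clustering, with the changed genes, fibroblast-like cells made up 31.4%, 2.36% and 9.03% and pericyte-like cells 2.20%, 17.0% and 6.72%, and no direction is read for fibroblast-like cells, whose shares turned with the clustering. Clusters left without a name held 67.2%, 59.6% and 74.0% in the clustering without the changed genes. In the planned clustering they held 38.3%, 55.0% and 72.0%. No test was run on shares.

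Shares of cells with a UMI of a gene are given with each cell thinned to 1000 UMIs, which left out 87, 82 and 110 cells. A UMI of the proliferation genes Mki67 or Top2a was found in 5.80% of control cells (95% exact interval 3.35 to 9.24%), 17.9% of Dox replicate 1 (14.8 to 21.3%) and 23.8% of Dox replicate 2 (21 to 26.7%), and in 15.2%, 40.4% and 53.7% of unthinned cells. In thinned supporting cell-like cells the shares were 4.00%, 3.92% and 0%, the last allowing a share of up to 11.5%. The shares over all cells include a cluster of little Malat1 led by mitotic genes, with 4, 37 and 65 barcodes before thinning. Those barcodes may not be whole cells. Shares over all cells also mix changes within cells with changes in makeup, so they give no rate of dividing cells. Notch1 was found in 12%, 37.3% and 26.9% of thinned supporting cell-like cells and in 35.5%, 83.1% and 55.2% unthinned, at median depths of 1590, 8201 and 14149 UMIs. No class is known from the labels to lack the transgenes, so no background share can be given. In macrophage-like cells the thinned Notch1 shares were 5.00%, 21.1% and 20.8% at median depths of 7810, 6991 and 21458 UMIs.

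Hes5 was found in 0%, 17.6% and 15.4% of thinned supporting cell-like cells and in 0% of macrophage-like cells of every library. A UMI of Myc was found in 2.54%, 7.22% and 6.20% of all thinned cells and in 21.2%, 47.0% and 54.2% unthinned. Atoh1, the transcription factor that starts hair cell formation, was found in 0 of 363, 0 of 636 and 0 of 997 unthinned cells, and in thinned cells its absence allows shares of up to 1.09%, 0.542% and 0.338% of cells with a UMI. Intervals and limits cover counting error only.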

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

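The tests weighed here were chosen only after the results were seen, except the share of calls on the X and Y chromosomes, which was set down before it was computed, and the planned test of the difference between classes.

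Several genes that the rule took in supporting cell-like cells responded differently to Dox there and in glia-like cells. The class-by-treatment test was used, whose p-values rest on a spread pooled over genes. The rule took these genes by the size or p-value of their effect in supporting cell-like cells, so the differences are in part selected for. Ednrb is on no fixed list and was taken as a large fall. Relative to glia-like cells, the log2 effect in supporting cell-like cells was lower for Ednrb by a difference of -3.45, for Hspa1a of -2.98, for the potassium channel gene Kcnj10 of -2.71, for Hspa1b of -2.44 and for the cell cycle inhibitor gene Cdkn1a of -2.21. It was higher for the glutathione transferase genes Gstm1 and Gsta4 by 6.29 and 3.57, for Sox2 by 3.36, for the lactate transporter gene Slc16a3 by 2.67, for Nr2f2 by 2.38 and for Nfkbia by 1.94. Smaller positive differences were found for Bax (1.53), the glycolysis genes Gpi1 (1.30) and Pgk1 (1.12) and mt-Nd3 (1.29). Gstm1 and Gsta4 rest on as few as 4 UMIs in 1 arm.

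Barcodes that the cell filters left out carried Notch1 at 308 CPM in Dox replicate 1 (exact Poisson interval 249 to 375) and 220 CPM in Dox replicate 2 (148 to 314), against 7.56 CPM in the control (0.191 to 42.1, on 1 UMI).

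Ribosomal protein genes were higher in Dox supporting cell-like cells. In thinned cells, which have equal weight, the lowest member of the list still stood at 0.47 on the log2 scale. Thinning leaves the expected share of each gene in a cell unchanged. It therefore cannot test a cause that goes with the number of UMIs per cell, which stays open. The weight of a few deep control cells stays open: among control cells with fewer than 5000 UMIs the median share was 7.65%, within the quartiles of Dox replicate 1, while deep cells stood at 4.28% in the control and 12.2% in each Dox library. A difference between whole libraries also stays open, since the rise in macrophage-like cells was 0.234 times that in supporting cell-like cells in sums and 1.02 times in thinned cells. An effect of the transgenes, the biological explanation the design gives, cannot be told apart from these in 1 control library. It also cannot be told apart from an effect of Dox itself, since no Dox-treated culture lacked the transgenes.

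A pair of clusters with 188 and 106 barcodes held little Malat1, at 168 and 745 CPM, and the smaller was led by mitotic genes such as Cdk1 and Ube2c. Free RNA in droplets is argued against, since summed markers of glia, macrophages and fibroblasts reached at most 0.386 times their level in the whole Dox libraries, and few UMIs per barcode by the shallowest cluster, where Malat1 was at 22208 CPM. Whole cytoplasm without its nucleus is also argued against, since the median mitochondrial share in the Dox libraries was at most 0.0879 times that of the whole library (0.871 times in the 4 control barcodes of the smaller cluster). Parts of the cytoplasm with neither nucleus nor most mitochondria may remain, a hypothesis found and tested on the same data, with the nuclear RNAs Neat1, Kcnq1ot1 and Xist at most at 0.0923 times their level in the whole Dox libraries, while the few control barcodes had Neat1 at 0.451 times on 4 UMIs in the larger cluster and Xist at 0.849 times on 1 UMI in the smaller. No biological explanation was tested.

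A different mix of male and female mice could have given calls in supporting cell-like cells. Of 610 called genes 18 lay on the X or Y chromosome, 2.95%, against 255 of 8321 tested, 3.06%, so the share was not raised. This cannot exclude sex as a source, since the share does not cover genes on other chromosomes that sex may affect. The Dox libraries also differed from each other, with Y-linked UMIs in 13.1% and 0.301% of cells against 23.1% in the control. Sex therefore stays open.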

How the results depend on the processing

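Tests under total count scaling, with cells of little Malat1 left out, with clustering without the changed genes, and all alternatives in glia-like and macrophage-like cells were chosen after seeing the data. No paired analysis was possible because the control has 1 library. No called gene of supporting cell-like, glia-like, macrophage-like or all cells turned with either Dox library left out, a weak check, since calls need Dox libraries that agree and the lone control cannot be left out.

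Supporting cell-like calls numbered 239 with DESeq2, 985 with total count scaling, 1000 at resolution 2, 1095 with the strict filter, 276 with cells of little Malat1 left out, 92 of 479 tested in thinned cells, 1298 when clustered without the changed genes (597 of the 610 among them) and 0 with each library clustered alone (edgeR, 1277 unadjusted, 168 by DESeq2). Glia-like calls numbered 379 with DESeq2's size factors, 380 without the low-count filter, 175 with DESeq2 and 119 thinned. Macrophage-like calls numbered 0 without the low-count filter (edgeR, 593 unadjusted, 25 by DESeq2), 0 with the strict filter (508 unadjusted, 25 by DESeq2), 25 with DESeq2, 44 with the legacy fit, 157 with total count scaling, 160 without cells of little Malat1, 26 thinned and 61 when clustered without the changed genes. With doublets left out, macrophage-like calls numbered 121, of which 80 were among the 103 of the main setting. All cells gave 888 calls thinned. Fewer genes were tested in thinned cells, and the cause was not tested elsewhere. Camera's 7 lists became 0 with an estimated correlation, a form that 1 residual degree of freedom leaves hardly able to call a list, and 0 with fry. The ribosomal median in supporting cell-like cells was 2.07 without cells of little Malat1.

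The shares of supporting cell-like cells were 9.37%, 16.2% and 9.03% at resolution 2, and 10.7%, 9.43% and 4.31% with each library clustered alone. Unthinned shares were 35.5%, 83.1% and 55.2% for Notch1 in supporting cell-like cells and 15.2%, 40.4% and 53.7% for Mki67 or Top2a.

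Reversed log2 values in supporting cell-like cells were, with each library clustered alone, -0.22 (Plk2), -2.40 (Itih5), -0.51 (Mmp15), -0.14 (Cib2) and -0.25 (Ccnd1). Cib2 was also at -1.46 with the strict filter, -1.61 at resolution 2 and -0.99 when clustered without the changed genes. In thinned cells Pgk1 was at -0.17 and H2-D1 at 0.22, and elsewhere Myc at -1.20 and Ifi27 at 1.12 (glia-like), Tnf at 1.24 (macrophage-like) and Tagln at 0.13 (all cells). The cause was not tested. Named-gene values otherwise kept side and direction in 1727 cases in supporting cell-like cells, against 204 weaker, 90 stronger and 40 moved. Control values of supporting cell-like cells rest on 261383 UMIs.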

Other observations

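The tests of the Epcam-positive clusters, of single unnamed clusters and of fibroblast-like cells were chosen only after the cells had been clustered and seen.

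Clusters were called positive for the epithelial adhesion gene Epcam where at least 40% of cells had a UMI of it and the median depth was at least 1000 UMIs. They held 85, 351 and 664 cells in the control and Dox libraries. The supporting cell-like class made up 31, 59 and 29 of these, and the other clusters held too few fixed markers to be named. The clusters with little Malat1 were among them, with 15, 91 and 82 barcodes in the larger and 4, 37 and 65 in the smaller. The depth limit left out a shallow cluster with an Epcam UMI in 47.8% of its cells, which held 74 control cells and 33 and 50 Dox cells. Summed over the Epcam-positive clusters, Notch1 was at 60.2, 481 and 345 CPM in the control and Dox libraries, a log2 fold change of 2.78 (SE 0.27, adjusted p = 0.00716), and Myc at 15.8, 57.8 and 55.7 CPM, a log2 fold change of 1.85 (SE 0.20, adjusted p = 0.00889), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. All 28 S phase genes rose (median 2.36, camera adjusted p = 1.94e-10) and 27 of 28 G2/M phase genes (median 1.75, camera adjusted p = 9.82e-10), with Mki67 at 2.22 and Mcm6 at 2.42, named here after their values were seen. All 26 ribosomal protein genes rose (median 1.51), as did 26 of 30 MYC-responsive growth genes with 1 fallen (median 1.88). Of 20 interferon-stimulated genes 12 fell (median -2.38), of 18 unfolded protein response genes 11 fell (median -0.56), and of 21 mature supporting cell genes 5 fell and 1 rose (median -1.85). With an estimated correlation the adjusted p was 0.83 for each of these lists. In all, 1641 genes rose and 1124 fell of 13531 tested, and DESeq2 called 1924. With the clusters of little Malat1 left out 2867 genes were called, 2698 of them shared, and 28 S phase, 26 G2/M phase and 26 ribosomal protein genes rose, with an adjusted p of 0.865 with an estimated correlation for each list. These sums mix clusters whose shares differ between libraries.

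The same lists were tested within single clusters, of which clusters 9 and 11 held 15 and 18 control cells, below the minimum of 20 set for named classes. In cluster 9, led by Epyc, Lum, Aqp4 and Otogl, 10 of 26 G2/M phase genes and 12 of 27 S phase genes rose, while 8 of 17 mature supporting cell genes fell and 1 rose, with an adjusted p of 0.669 with an estimated correlation for each list. In cluster 11, led by Vmo1, Gpx3 and Lrp2, 27 of 28 G2/M phase genes rose, 18 of 20 interferon-stimulated genes fell (median -2.81) and 14 of 18 unfolded protein response genes fell (median -0.88), with an adjusted p of 0.87 with an estimated correlation for each. A pair of cycling epithelial clusters, led by histone genes, held 0 control cells, 29 and 73 Dox cells in the first and 6 and 59 in the other. In fibroblast-like cells edgeR's quasi-likelihood test called 0 genes (2047 at an unadjusted p of 0.05 or less, and 91 by DESeq2), and the control and Dox cells of that class lay mostly in different clusters, with 81, 1 and 1 cells in the first and 33, 14 and 89 in the other.

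Sex-linked genes differed between libraries. Xist, expressed in female cells, was at 487, 692 and 736 CPM, and a UMI of 4 Y-linked genes was found in 84 of 363 control cells (23.1%), 83 of 636 cells of Dox replicate 1 (13.1%) and 3 of 997 cells of Dox replicate 2 (0.301%).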
